A study of Mus musculus with 5 samples.

How the data were processed

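The deposited data were 5 droplet libraries made with 10x Genomics 3' chemistry, 1 from PBS-treated and 4 from decoy-treated mice, each with 32285 genes. Values in the deposited matrices were counts, that is, whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. The matrix headers named Cell Ranger 5.0.0, whereas the notes of the authors listed Cell Ranger 3.1, Seurat 4 and DESeq2 and the mm10 build; the role of each tool and the annotation were not given in the sources used here. The lowest barcode total was 500 UMIs in 4 libraries and 502 in Decoy 6, so a floor had been applied before deposit. Gene coordinates were taken from the GENCODE vM21 annotation of the same build, in which 32158 genes, 99.6%, were found by identifier. The 78 symbols used by more than 1 gene had the identifier appended.

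Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrial genes were kept. Doublets, meaning droplets that hold 2 cells, were scored per library with scrublet as run by scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. The automatic threshold marked 6.30% of the PBS barcodes but between 0.0160% and 0.361% in the Decoy libraries, against expected rates of 15.5% and of 1.96% to 5.49%, so it did not separate doublets in the Decoy libraries. The marked barcodes were removed. The counts of called genes, the lists over all kept cells and the class shares were repeated with the highest scores removed at the expected rate; the lists within classes, the differences between classes and the cycling shares were not.

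Kept cells were scaled to 10000 UMIs and log-transformed. The 2000 most variable genes, chosen within libraries after leaving out mitochondrial, ribosomal, cell cycle, interferon and NF-kB genes, gave 30 principal components, a graph of 15 neighbours and Leiden clusters (leidenalg 0.10.2) at a resolution of 0.5. Clusters were named from 16 marker lists, requiring at least 3 markers found in at least 10% of cells and at least 2-fold above the mean of the other clusters. After the clusters had been seen, those whose mean profiles correlated at 0.85 or more were merged before naming, and low-UMI clusters with no marker among their 10 leading genes were left unnamed. No cluster took its name from the marker lists for stem and progenitor cells, monocytes, megakaryocytes, eosinophils, NK cells or endothelial and stromal cells. The names mean resemblance in these markers, not a measured lineage.

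The library was the replicate in every test. UMI counts were summed over the cells of each library, for all kept cells and for each class with at least 50 cells in the PBS library and in at least 3 Decoy libraries. Genes were filtered with filterByExpr, scaled by TMM and tested with the two-sided quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call. Levels are CPM, the count of a gene over the library total scaled by TMM, times 1e6. The levels of Xist, Kit and the Y-linked genes across classes were scaled by the total alone. So were the levels given for Igkc and C1qa in the progenitor-like, T cell-like and neutrophil-like classes. The same holds for levels in progenitor-like cells split by Xist and Y-linked UMIs. With 1 PBS library the spread came from the Decoy libraries alone, 3 residual degrees of freedom over all kept cells, and the PBS library was assumed to vary like them. The labels do not say whether each library came from a separate animal, so p-values measure only the spread between these libraries.

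Each of 21 gene lists was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes and a prior count of 2, adjusted over the lists. Calls were repeated with an estimated correlation and with fry, which asks only whether the genes of a list move one way on balance. Counts of called members are given over all genes tested and adjusted over the list alone. In the type I interferon list Mx1 and Mx2 were not analysed here. The lists, markers, main tests and 38 alternatives were chosen before the data were examined, unlike some tests of explanations, as said beside them. So was the rule for named genes: 16 fixed genes whatever their result, the 8 called genes with the largest change in each direction among those with a mean of at least 20 CPM and every Decoy library on the same side, and up to 4 called members of each list, or 2 abundant members where none was called. Other genes named for their values were chosen after these were seen. A further 17 alternatives were added after the data had been seen.

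Shares of classes and of cycling cells were compared with a two-sided exact permutation test over the 5 choices of the single library, which cannot give a p below 0.2. Shares of single libraries carry 95% exact Clopper-Pearson intervals, and a share of 0 is given with the limit that 3 counts would allow; both cover counting error only. Cell cycle phase was called with scanpy after thinning each cell to 3000 UMIs, leaving out cells below that depth. The origin of cells was read from Xist, which is transcribed from the inactive X chromosome of female cells, and from the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. RNA of other cells in the mast cell and basophil-like class was estimated from the Y-linked genes, and RNA of leukaemic cells in the other classes from Xist, and the scaled profile was taken out in an alternative. Differences between classes in their response were tested with an interaction term in the same model, without a term for the library, and again with library as a block.

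Alternatives included DESeq2 1.42.0, limma-voom, a robust fit, other scaling, gene filters and cell filters, thinning to the smallest library, other clustering settings, and leaving out each Decoy library in turn. The procedure was tested on simulated data in which 200 genes were changed. In the mast cell and basophil-like class 98.5% of 2-fold changes were recovered, in the granulocyte-monocyte progenitor-like class 68.7%, and over all kept cells 1.49%, with 21.2% of 4-fold changes. Recovery of 2-fold changes was 73.1% in the erythroid-like, 34.3% in the macrophage-like, 29.9% in the B cell-like and 1.49% in the T cell-like class, and 0 of 67 were recovered in the neutrophil-like class. A list raised 1.5-fold in the simulation was called in every class, whereas over all kept cells its adjusted p from camera was 0.0974. In any fit 0 of 20 unchanged lists were called. The simulated genes were drawn independently of each other, so these list results do not measure false calls among correlated genes.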

Results

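Mice of the C57BL/6 strain were injected intravenously with CMM acute myeloid leukaemia cells, a mouse inv(16) leukaemia marked with green fluorescent protein (GFP). Treatment began when about 1% of blood cells carried GFP, and consisted of 3 intravenous injections, every other day, of PBS or of a CpG-STAT3 decoy. The decoy is a DNA oligonucleotide that binds the transcription factor STAT3, joined to a CpG oligonucleotide that binds the endosomal receptor TLR9. Cells positive for GFP and for the receptor c-Kit were sorted from spleens, and their messenger RNA was counted per cell as unique molecular identifiers (UMIs). There were 5 libraries, 1 from PBS (n = 1) and 4 from decoy treatment (n = 4), named Decoy 2, Decoy 3, Decoy 5 and Decoy 6. The question was how STAT3 inhibition with TLR9 stimulation changes the expression programme of the leukaemic cells, including differentiation that depends on the transcription factor Irf8 and regulators of chromatin.

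The PBS library held 579333323 UMIs in 19337 barcodes. Decoy 2 held 234251245 UMIs in 6867 barcodes, whereas Decoy 3, Decoy 5 and Decoy 6 held 56490098, 83316079 and 85354471 UMIs in 2454, 4634 and 3743 barcodes. The share of barcodes removed for a high mitochondrial share was 8.34% in PBS and 5.94%, 12.3%, 16.2% and 11.2% in the Decoy libraries in the order of their numbers. After filtering 16134 PBS cells remained, with a median of 30728 UMIs. The Decoy libraries kept 6251, 1934, 3605 and 3216 cells, with medians of 36499, 22327, 14005 and 23921.5 UMIs.

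Cells with some mast cell and basophil genes formed most of the PBS library and a variable part of the Decoy libraries. This class was led by Fcer1a and Ms4a2, subunits of the high-affinity IgE receptor, by Cpa3, a mast cell protease, and by Xist. Only Fcer1a, Ms4a2 and Cpa3, 3 of the 10 markers of its list, passed the naming rule. The basophil protease genes Prss34 and Mcpt8 stood at 0.169 and 0.0884 CPM in its PBS cells, scaled by the total alone. The class held 91.7% of PBS cells (Clopper-Pearson 95% interval 91.2% to 92.1%). It held 83.6% of Decoy 2, 44.2% of Decoy 6, 19.6% of Decoy 3 and 0 of 3605 cells of Decoy 5, which allows a share of up to 0.0832%. The Decoy mean was 36.8% ± 36.0 (SD, n = 4), and Decoy minus PBS was -54.8 points (exact permutation p = 0.4). Without Decoy 2 the Decoy mean was 21.3% and the difference -70.4 points. The lowest Decoy share was 0.388% at a clustering resolution of 0.3 and 0.166% at 1.0, so that of Decoy 5 depends on the clustering beyond its counting limit.

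The remaining cells mostly carried genes of other blood lineages, both mature and progenitor. Most of these classes took a larger share of every Decoy library than of PBS. Macrophage-like cells made up 0.781% of PBS cells and 20.9% ± 12.7 (SD, n = 4) of Decoy cells (exact permutation p = 0.2). T cell-like cells made up 0.397% and 3.71% ± 1.70 (SD, n = 4, exact permutation p = 0.2). B cell-like cells were 1.23% of PBS and 17.3% ± 12.7 (SD, n = 4) of Decoy cells, granulocyte-monocyte progenitor-like cells 0.651% and 6.63% ± 3.31, and neutrophil-like cells 0.390% and 3.93% ± 1.60; the exact permutation p was 0.4 for each. Plasma cell-like cells were 0 of 16134 in PBS, which allows up to 0.0186%, and 3.21% ± 2.12 (SD, n = 4) in the Decoy libraries (exact permutation p = 0.4). With predicted doublets kept the PBS share was 0.0290%, above that limit. Conventional and plasmacytoid dendritic-like cells each made up 0.0124% of PBS and 0.308% ± 0.237 and 0.316% ± 0.252 (SD, n = 4) of Decoy cells (exact permutation p = 0.4 for both). At a clustering resolution of 1.0 the plasmacytoid dendritic-like class held 0.335% of PBS and 1.57% ± 0.916 of Decoy cells (SD, n = 4), and no cluster was named conventional dendritic. Erythroid-like cells were 3.64% of PBS and 5.56% ± 4.18 (SD, n = 4) of Decoy cells (exact permutation p = 0.6), and unnamed cells 1.21% and 1.31% ± 0.993 (exact permutation p = 1). With 1 PBS library the smallest p this two-sided test allows is 0.2, so no share could pass 0.05.

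**Figure D1:**
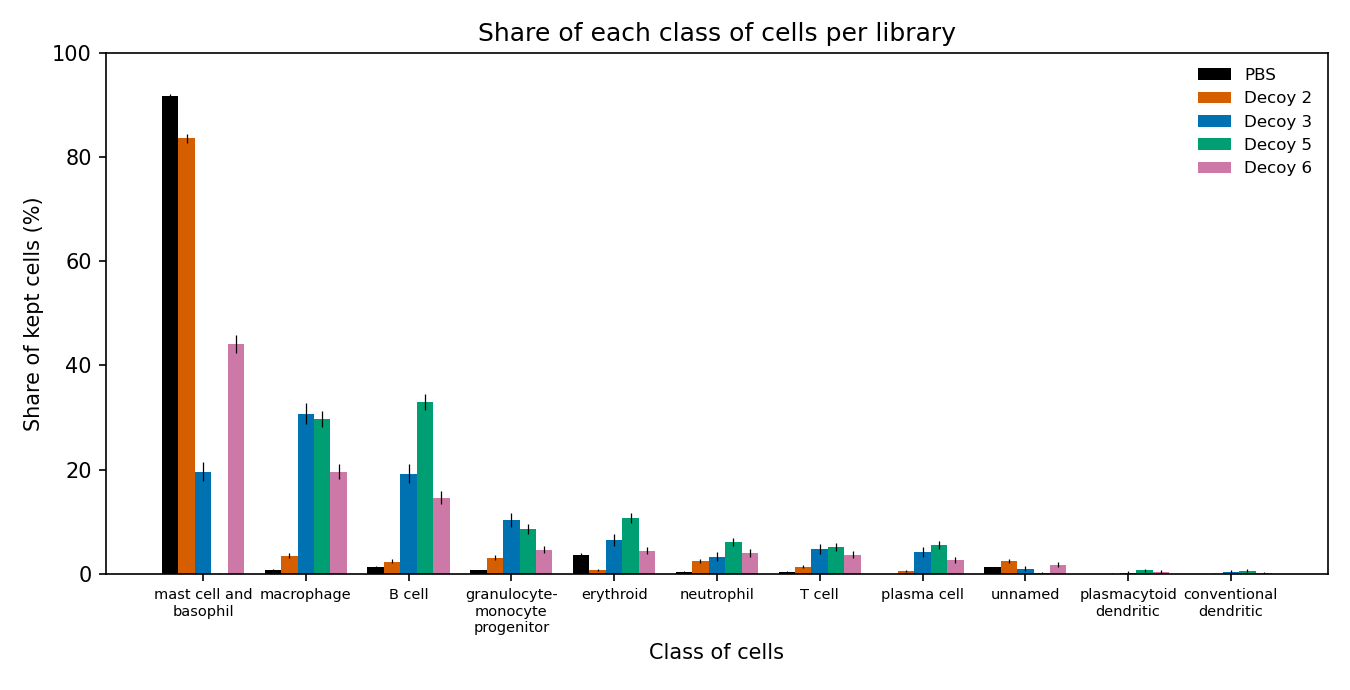
Bars give the share of kept cells (%) in each class for the PBS library and the 4 Decoy libraries, with 95% Clopper-Pearson intervals that cover counting error only. The mast cell and basophil-like class holds 91.7% of PBS and between 0 and 83.6% of the Decoy libraries.

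Shares were also taken among the cells of the other named classes, 1147 in PBS, with unnamed cells left out. Erythroid-like cells were 51.2% of them in PBS and 7.96% ± 2.43 (SD, n = 4) in the Decoy libraries (exact permutation p = 0.2). Macrophage-like cells were 10.99% and 32.3% ± 6.40 of them (SD, n = 4, exact permutation p = 0.2). Plasma cell-like cells were 0 and 4.93% ± 0.561 (SD, n = 4, exact permutation p = 0.2), B cell-like cells 17.3% and 25.3% ± 6.73 (exact permutation p = 0.6), and progenitor-like cells 9.15% and 13.1% ± 6.49 (exact permutation p = 0.8). The clusters that made up the erythroid-like and macrophage-like classes differed in weight between the treatment groups. Of the 587 erythroid-like cells in PBS, 550 lay in a haemoglobin-rich cluster with a median of 6566 UMIs, while those of the Decoy libraries lay mostly in a cluster with Car1 and the erythroid transcription factor Klf1 and a median of 54779.5 UMIs. Of the macrophage-like cells in PBS, 71 of 126 lay in a cluster with a median of 1769 UMIs. Most of those in the Decoy libraries lay in a cluster with a median of 22270.5 UMIs, which also held the other 55 PBS cells.

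Xist and the Y-linked genes separated the mast cell and basophil-like class from every other named class. In that class Xist reached 978 CPM in PBS and 879, 1086 and 1031 in Decoy 2, Decoy 3 and Decoy 6, while the Y-linked genes together stood at 0.223, 0.189, 0.629 and 0.542. In the other named classes together the Y-linked genes stood at 116 CPM in PBS and 71.4, 128, 131 and 121 in the Decoy libraries, and Xist at 60.3, 123, 21.96, 0.0743 and 68.3. The few unnamed cells resembled the mast cell and basophil-like class in this, with Xist at 289 in PBS and 1633, 1303 and 3286 in Decoy 2, Decoy 3 and Decoy 6, and Y-linked genes at 0.797, 0, 0 and 5.35. Kit, which encodes c-Kit, was at 51.5 CPM in the mast cell and basophil-like class of PBS and at 51.9, 47.1 and 43.6 in Decoy 2, Decoy 3 and Decoy 6. In the other classes together Kit was at 7.31 in PBS and at 15.7, 13.7, 10.1 and 11.8 in the Decoy libraries. Among them, erythroid-like cells had Kit at 5.43 in PBS, 29.5 in Decoy 2 (42 cells) and 45.8 in Decoy 3 (125 cells). A high Kit level was thus not confined to the mast cell and basophil-like class. The share of cells with a Kit UMI was 64.4% in the mast cell and basophil-like class of PBS, at a median of 31954 UMIs, and 4.71% in the other classes, at a median of 6606. In B cell-like cells, which should lack Kit, 2 of 198 PBS cells had a Kit UMI, and between 0 and 5.44% of the cells of each Decoy library, at median depths of 3908.5 to 9094 UMIs. Over the Decoy libraries the other classes had a Kit UMI in 7.53% to 14.5% of cells, at median depths of 14015 to 20503.5 UMIs.

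**Figure D2:**
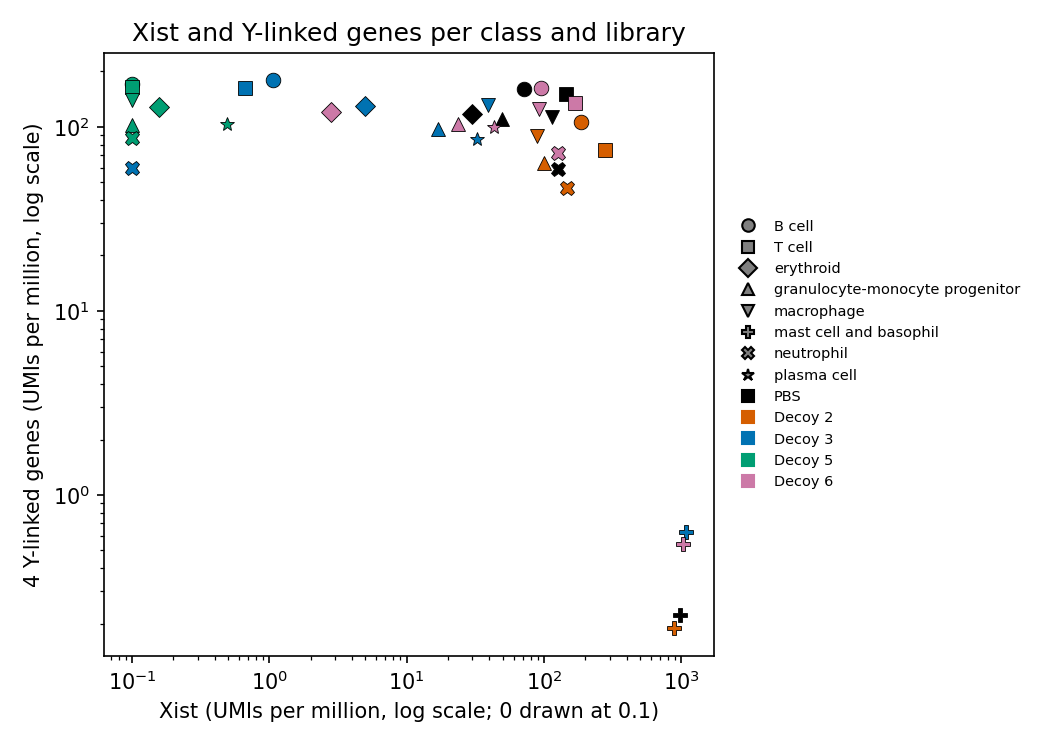
Each point gives Xist against the sum of 4 Y-linked genes (CPM, log axes) in 1 class of at least 50 cells in 1 library, with 0 drawn at 0.1. The mast cell and basophil-like class lies at 879 to 1086 for Xist and 0.189 to 0.629 for the Y-linked genes.

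Over all kept cells, myeloid differentiation and antigen presentation genes had higher levels in the Decoy libraries than in PBS, with a wide spread that left no gene past the threshold. Irf8 (ENSMUSG00000041515, mm10 chromosome 8, 120736358 to 120756694, + strand), a transcription factor of monocyte and dendritic cell development, stood at 3.85 CPM in PBS and 128 ± 85.5 in Decoy (SD, n = 4), a log2 fold change of 5.05 ± 1.63 (SE, adjusted p = 0.46602). Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652, + strand), the invariant chain of MHC class II, stood at 54.7 and 1725 ± 1108 (log2 fold change 4.98 ± 1.72, SE, adjusted p = 0.46602). Mpo, the neutrophil granule peroxidase, was at 5.09 and 91.0 ± 58.2, and Socs3, a STAT3 target that restrains cytokine signalling, at 0.918 and 19.4 ± 12.3 CPM. Tlr9, the receptor for CpG DNA, was at 0.0139 CPM in PBS, which was 7 UMIs, and 0.690 ± 0.449 in Decoy. The myeloid factors Cebpa, Id2 and Spi1 had log2 fold changes of 3.98, 1.64 and 0.88.

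Stat3 (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540, - strand) differed little over all kept cells, at 67.5 CPM in PBS and 69.8 ± 5.32 in Decoy (SD, n = 4, log2 fold change 0.05 ± 0.15, SE, adjusted p = 0.846). Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722, + strand) stood at 51.2 and 27.3 ± 17.3 (log2 fold change -0.91 ± 0.82, SE, adjusted p = 0.556), lower in each Decoy library. Runx1, a partner of the Cbfb protein that inv(16) alters, had a log2 fold change of -1.10, the DNA methyltransferase Dnmt1 -0.61, the stem cell factor Gata2 -0.56, Myc -0.49, Cbfb -0.08 and the progenitor marker Cd34 1.48, with adjusted p between 0.477 and 0.741.

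Of 16001 genes tested over all kept cells edgeR called 0, with a smallest adjusted p of 0.46602, and 1671 had an unadjusted p under 0.05, of which 1619 were higher in Decoy. The voom method called 0 and DESeq2 2076, of which 2067 were higher, among them Irf8 (adjusted p = 0.000824), Cd74 (0.00157), Tlr9 (0.00147) and Mpo (0.00148). One library decided the edgeR count: without Decoy 2 it was 2466, of which 2404 were higher, and included Irf8 at a log2 fold change of 5.38 (adjusted p = 0.0202), Cd74 (0.0180), Socs3 (0.0178), Mpo (0.0311), Tlr9 (0.0209), Cebpa (0.0287), Id2 (0.0224) and Spi1 (0.0259). The single PBS library was assumed to vary like the Decoy libraries.

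Of the 21 gene lists, 14 were called over all kept cells, 9 of them higher in Decoy. The median log2 fold change was 4.91 for MHC class II presentation (15 of 15 higher, adjusted p = 5.97e-07), 4.27 for the interferon gamma response (adjusted p = 5.6e-08), 3.70 for myeloid differentiation regulators (20 of 20 higher, 1.03e-07), 3.26 for granule proteins of granulocyte-monocyte progenitors (3.1e-05) and 2.97 for the NF-kB and TLR response (1.99e-05). It was 2.41 for the type I interferon response (27 of 28 higher, 5.6e-08), 2.26 for immune checkpoint and co-stimulation (0.00164), 1.90 for MHC class I presentation (6.9e-07) and 1.09 for STAT3 targets, of which 16 were higher and 7 lower (0.0196). Lists called lower were cytosolic ribosomal proteins (63 of 78 lower, median -0.32, 2.95e-05), S phase (37 of 42, -0.24, 6.49e-05), G2 and M phase (41 of 50, -0.20, 0.000175), mitochondrial transcripts (-0.18, 0.0356) and chromatin and DNA methylation regulators (14 of 20, -0.16, 0.0472). Each of the 14 calls was lost with an estimated correlation (adjusted p = 0.59 for all), and fry called 0. Adjusted over the list alone, 11 granule genes and 0 genes of any other list passed. The chromatin call was lost without Decoy 3 (adjusted p = 0.0520), without Decoy 5 (0.0778) or without Decoy 6 (0.0855), and that of mitochondrial transcripts without Decoy 5 (0.103) or Decoy 6 (0.0855).

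The other 7 lists were not called over all kept cells. Their adjusted p was 0.156 for TLR9 pathway components, 0.245 for the stem and leukaemia programme, for p53 and apoptosis and for immediate early and heat shock genes, 0.251 for respiratory chain nuclear subunits, 0.329 for glycolysis and hypoxia and 0.363 for the unfolded protein and integrated stress response. For the stem and leukaemia programme the test pointed lower and the median was -0.58, but the mean was 0.53. For the respiratory chain, which was called without Decoy 2 (adjusted p = 0.0276), the test pointed lower and the median was -0.05, but the mean was 0.07.

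Within the mast cell and basophil-like class, interferon-induced genes rose in the Decoy libraries, while Kit, Stat3 and Dnmt1 stayed close to PBS. Granulocyte genes were called higher too, with few or no UMIs beyond those estimated for RNA of other cells in the droplets. The comparison asks what treatment changed in the class that carries Xist. It used PBS (n = 1) and Decoy 2, Decoy 3 and Decoy 6 (n = 3). Ifitm3 (ENSMUSG00000025492, chromosome 7, 141009586 to 141010770, - strand), which blocks virus entry, rose from 47.4 to 151 ± 35.5 CPM (SD, n = 3, log2 fold change 1.67 ± 0.23, SE, adjusted p = 0.0112). Oasl2 (ENSMUSG00000029561, chromosome 5, 114896936 to 114912234, + strand), of the antiviral oligoadenylate synthetase family, rose from 1.48 to 5.79 ± 1.32 (1.92 ± 0.25, SE, adjusted p = 0.0111). Other interferon-induced genes that rose were Oas3 (log2 fold change 2.15), Ifi27l2a (2.54), the transcription factor Irf7 (1.82) and Xaf1 (1.42). Among granulocyte and macrophage genes, S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035, + strand) stood at 7.50 and 27.4 ± 9.84 (1.90 ± 0.30, SE, adjusted p = 0.0231), and its partner S100a9 (1.42), Lyz2, which encodes lysozyme (2.20), the granule protease gene Prtn3 (1.38), Plac8 (2.38) and the chemokine gene Ccl5 (2.48) were also called higher. After the profile of the other cells was taken out, 0 UMIs of S100a8 and S100a9 were left in any library, from 3900 and 4761 in PBS and 7873 and 6779 in Decoy 2, and at most 7 of Prtn3, 11 of Plac8 and 72 of Lyz2 in a Decoy library. Of the interferon-induced genes, Ifitm3 kept 6955 of 7242 UMIs in Decoy 6 and Oasl2 221 of 231. Igkc (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966, + strand), the immunoglobulin kappa constant gene of B cells, had the largest difference of the named genes, at 3.33 and 67.7 ± 41.0 (4.31 ± 0.67, SE, adjusted p = 0.0224).

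Some genes of the respiratory chain and of ribosomes rose in the same class, 3 of 71 and 10 of 77 members of these lists, whose calls were lost with an estimated correlation (adjusted p = 0.696 for both). Cox7a1 (ENSMUSG00000074218, chromosome 7, 30184144 to 30186078, + strand), a cytochrome c oxidase subunit, rose from 15.4 to 34.4 ± 2.59 CPM (SD, n = 3, log2 fold change 1.16 ± 0.13, SE, adjusted p = 0.00371). Pet100, an assembly factor of that complex, rose from 63.5 to 138 ± 16.9, and the complex I genes Ndufb1-ps and Ndufa1 from 315 to 657 ± 72.8 and from 191 to 337. The ribosomal protein genes Rps27 and Rps28 had a log2 fold change of 0.97 each, and Rpl39 and Rpl41 of 0.79 each. The rise was not confined to this class, since Pet100 and Ndufb1-ps had log2 fold changes of 0.75 to 1.48 and 0.85 to 1.24 in the B cell-like, T cell-like, progenitor-like, macrophage-like and neutrophil-like classes, whereas Cox7a1 varied there from -0.84 to 0.93 with an SE of at least 0.678. The 91 genes called higher in the mast cell and basophil-like class had short transcripts, with a median exon length of 1499 bases against 3901 for all genes tested. Lower genes were Tfrc (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794, + strand), the transferrin receptor that takes up iron, from 81.8 to 49.3 ± 2.87 (log2 fold change -0.73 ± 0.11, SE, adjusted p = 0.0193), and Gstp1 (ENSMUSG00000060803, chromosome 19, 4035407 to 4037985, - strand), a glutathione transferase, from 47.9 to 25.5 ± 4.07 (-0.90 ± 0.15, adjusted p = 0.0267). The spliceosome-associated gene Erh (-0.71), the osteopontin gene Spp1 (-0.68), Clint1 (-0.58) and Enah (-0.57) also fell. Tfrc and Erh were lower in the same 5 other classes too, by log2 fold changes of -1.79 to -0.67 and -1.07 to -0.51.

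**Figure D3:**
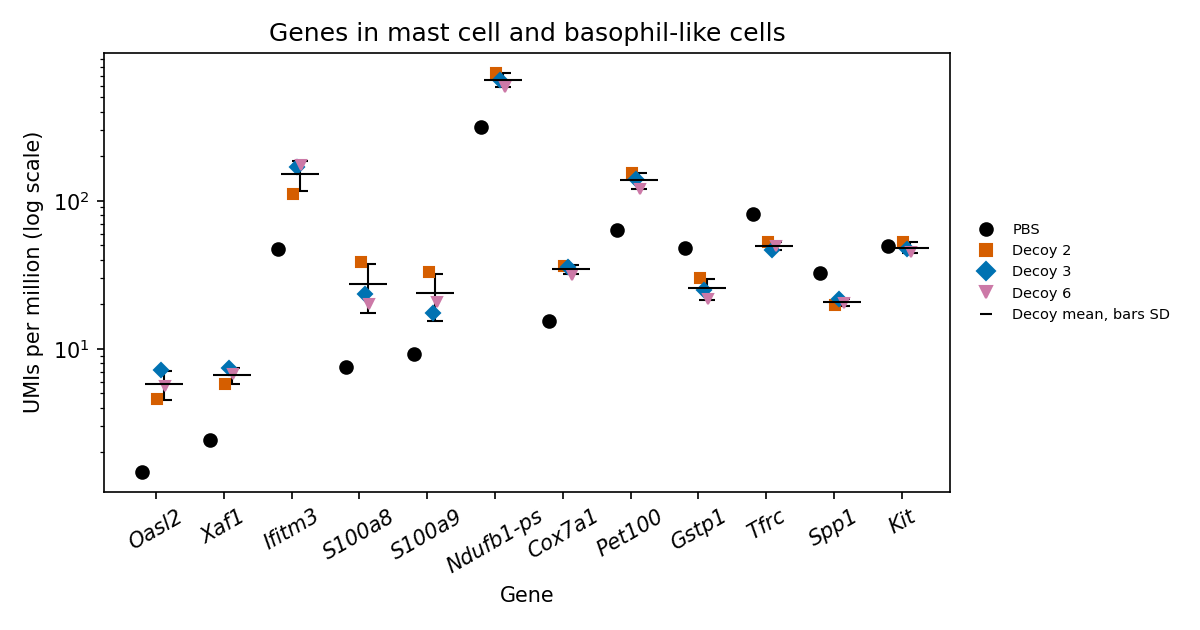
Levels (CPM, log axis) of 12 genes in the mast cell and basophil-like class, with a point per library and the Decoy mean with SD (n = 3). Ndufb1-ps stands at 315 in PBS and 657 on average in Decoy, and Tfrc at 81.8 and 49.3, while Kit stands at 49.3 and 48.2.

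Kit stood at 49.3 CPM in PBS and 48.2 ± 3.98 in Decoy in this class (SD, n = 3, log2 fold change -0.03, adjusted p = 0.984), Stat3 at 63.6 and 59.8 (-0.09, 0.882) and Dnmt1 at 231 and 230 (-0.01, 0.998). Irf8 had a log2 fold change of 1.31 ± 0.50 (SE, adjusted p = 0.402), at 0.350 CPM in PBS, which were 182 UMIs, and 0.524, 1.03 and 1.23 in the Decoy libraries. Cd74 had a log2 fold change of 1.22 ± 0.48 (SE, adjusted p = 0.433). Mpo (2.06), Cebpa (2.16), Socs3 (1.20), Id2 (0.36), Gata2 (0.28), Myc (0.24), Spi1 (0.15), Cbfb (0.07), Runx1 (-0.07) and Cd34 (-0.30) were not called.

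Of 14350 genes tested in this class, 91 were called higher and 9 lower. DESeq2 called 260 genes, voom 257 and the robust fit 189, and the count was 645 without Decoy 2, 151 without Decoy 3 and 216 without Decoy 6. Without Decoy 2 Irf8 (log2 fold change 1.71, adjusted p = 0.0353), Cd74 (1.64, 2.69e-09) and Id2 (0.42, 0.0462) were called, and without Decoy 3 Rpl39 (0.0580) and Rpl41 (0.0653) were not. Taking out the profile of the other cells left 57 higher and 8 lower, and turned Igkc to -1.63, Cd74 to -2.11 and Irf8 to -0.36, while Ccl5 (adjusted p = 0.933) and Lyz2 (0.406) lost their calls. The robust fit did not call Ifitm3 (adjusted p = 0.423), S100a8 (0.608), S100a9 (0.668), Irf7 (0.522) or Igkc (0.628). Cox7a1, Pet100, Ndufb1-ps, Ndufa1, Rps27, Rps28, Ccdc180, Tfrc and Erh were called under all 15 alternatives.

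In this class 11 of the 21 lists were called, 10 of them higher. The type I interferon response had a median log2 fold change of 0.93, with 25 of 28 members higher (adjusted p = 1.59e-11). Over all genes tested 7 of them were called, and adjusted over the list alone 17 were higher and 1 lower. Granule proteins had a median of 1.38 (adjusted p = 1.29e-05, 3 called, 7 adjusted over the list alone), a call lost with RNA of other cells taken out (0.977), and myeloid differentiation regulators of 0.84 (7.07e-06, 0 called, 3 adjusted over the list alone). The interferon gamma response (median 0.61, 4.6e-07) had 0 members called and 10 adjusted over the list alone, MHC class I presentation (0.31, 4.9e-06) 0 and 9, and MHC class II presentation (0.85, 0.0109) 0 and 1. STAT3 targets were higher in 17 of 20 members (median 0.30, adjusted p = 0.00101), with 2 called, S100a8 and S100a9, which kept 0 UMIs with RNA of other cells taken out, and the same 2 adjusted over the list alone. The list kept its call after that step (adjusted p = 0.00698). The NF-kB and TLR response (0.36, 0.00402) had 1 called member, Ccl5. Respiratory chain nuclear subunits (0.10, 7.07e-06) had 3 called, and adjusted over the list alone 19 higher and 1 lower; cytosolic ribosomal proteins (0.09, 9.27e-05) had 10 called and 14 adjusted over the list alone. G2 and M phase genes were lower (median -0.09, adjusted p = 0.0435). With an estimated correlation every call was lost, at adjusted p = 0.696 for 9 lists, 0.715 for the NF-kB and TLR response and 0.851 for G2 and M phase, and fry called 0.

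Of the lists not called in this class, chromatin and DNA methylation regulators had a median of -0.05 (adjusted p = 0.0826), glycolysis and hypoxia and immune checkpoint and co-stimulation an adjusted p of 0.0595 each, and immediate early and heat shock genes 0.0666. TLR9 pathway components stood at 0.672, with Irf7 called among them, the unfolded protein and integrated stress response at 0.65, S phase at 0.677, mitochondrial transcripts at 0.672, the stem and leukaemia programme at 0.85 and p53 and apoptosis at 0.851. In 4 of these the median, the mean and the test differed in sign, with medians of 0.00069 for the stem and leukaemia programme, -0.0041 for S phase, 0.02 for p53 and apoptosis and -0.03 for mitochondrial transcripts. The G2 and M phase call was lost without Decoy 3 (adjusted p = 0.349) or Decoy 6 (0.399) and on taking out the profile of other cells (0.0784), that of MHC class II without Decoy 6 (0.227) and on taking out the profile of other cells (0.720). Immediate early genes were called without Decoy 2 (0.0140), Decoy 3 (0.0287) or Decoy 6 (0.0354), checkpoint genes without Decoy 2 (0.0142) and glycolysis without Decoy 3 (0.0479) or with the profile of other cells taken out (0.0497). Scaled by library size only, chromatin and DNA methylation regulators were called lower (0.0308), and checkpoint (0.0217) and immediate early genes (0.0158) higher.

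In the granulocyte-monocyte progenitor-like class, MHC class II genes and Irf8 rose in the Decoy libraries, and Socs3 and other STAT3 targets fell. The class was led by the granule genes Prtn3, Ctsg, Mpo and Elane and the basophil protease genes Prss34 and Mcpt8. F13a1 and Fn1 of the monocyte list were also among the 10 leading genes of the class. It held 105 cells in PBS and 195, 198, 307 and 149 in the Decoy libraries (n = 4). At a clustering resolution of 1.0 it held 0.651% of PBS and 5.51% ± 2.42 of Decoy cells (SD, n = 4), and at 0.3 it was not named. At 0.3 the macrophage-like class held 1.43% of PBS and 27.5% ± 15.7 of Decoy cells (SD, n = 4). In the main setting it held 0.781% and 20.9%, so the border between the progenitor-like and macrophage-like classes is open. The fit was not repeated at these resolutions, so a changed mix of cells within the class was not tested. Of its cells with UMIs of Xist or of Y-linked genes but not both, 98.6% had the Y-linked genes in PBS and 92.0%, 82.5%, 100% and 99.2% in the Decoy libraries. H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823, - strand), a chain of the MHC class II molecule, rose from 54.4 to 448 ± 89.2 CPM (SD, n = 4, log2 fold change 3.04 ± 0.29, SE, adjusted p = 0.0109). H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674, + strand) rose from 33.8 to 285 ± 55.7, H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419, + strand) from 73.7 to 419 ± 78.7, and Cd74 from 263 to 1229 ± 216. Irf8 rose from 132 to 294 ± 41.8 (log2 fold change 1.15 ± 0.19, SE, adjusted p = 0.0436). Socs3 (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047, - strand) fell from 40.4 to 12.1 ± 2.81 (-1.76 ± 0.26, SE, adjusted p = 0.0324), and Id2 (ENSMUSG00000020644, chromosome 12, 25093799 to 25097140, - strand), an inhibitor of basic helix-loop-helix factors, from 114 to 49.7 ± 3.06 (-1.20 ± 0.11, adjusted p = 0.0109).

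Other genes that rose in this class were Cfb (ENSMUSG00000090231, chromosome 17, 34856374 to 34862518, - strand), complement factor B, from 11.9 to 103 ± 14.3 CPM (SD, n = 4, adjusted p = 0.00887), Lpl, the lipoprotein lipase gene (log2 fold change 2.43), the peptide exchange factor gene H2-DMb1 (2.04), the progenitor transcription factor Sox4 (2.25), Ly6i (2.93), H2-Q6 (2.39) and the interferon-induced Cmpk2 (1.28). The MHC class I gene H2-K1 (0.88), the peptide loading gene Tapbp (0.60) and the immunoproteasome genes Psmb8 and Psmb9 (0.57 each) rose as well. Il1r2 (ENSMUSG00000026073, chromosome 1, 40074079 to 40125231, + strand), the decoy receptor for interleukin 1, fell from 110 to 9.43 ± 4.46 (log2 fold change -3.56 ± 0.39, SE, adjusted p = 0.0148), and Ifitm1 fell from 2789 to 426 ± 156. Dmkn (-3.35), Lrg1 (-3.33), Ifitm6 (-1.96), Tfrc (-1.79), the NF-kB inhibitor gene Nfkbia (-1.54), the interleukin 4 receptor gene Il4ra (-1.22) and the haptoglobin gene Hp (-0.78) fell too. The chemokine gene Ccl4 was called lower (-3.48) but turned to 2.10 (adjusted p = 0.538) with the highest doublet scores removed at the expected rate. Not called were Cd34 (1.90, adjusted p = 0.0863), Kit (0.94, 0.435), Mpo (0.44, 0.503), Stat3 (-0.19, 0.405), Spi1 (-0.35, 0.229), Gata2 (0.26), Myc (0.23), Cebpa (-0.19), Dnmt1 (-0.11), Runx1 (-0.05) and Cbfb (-0.04).

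**Figure D4:**
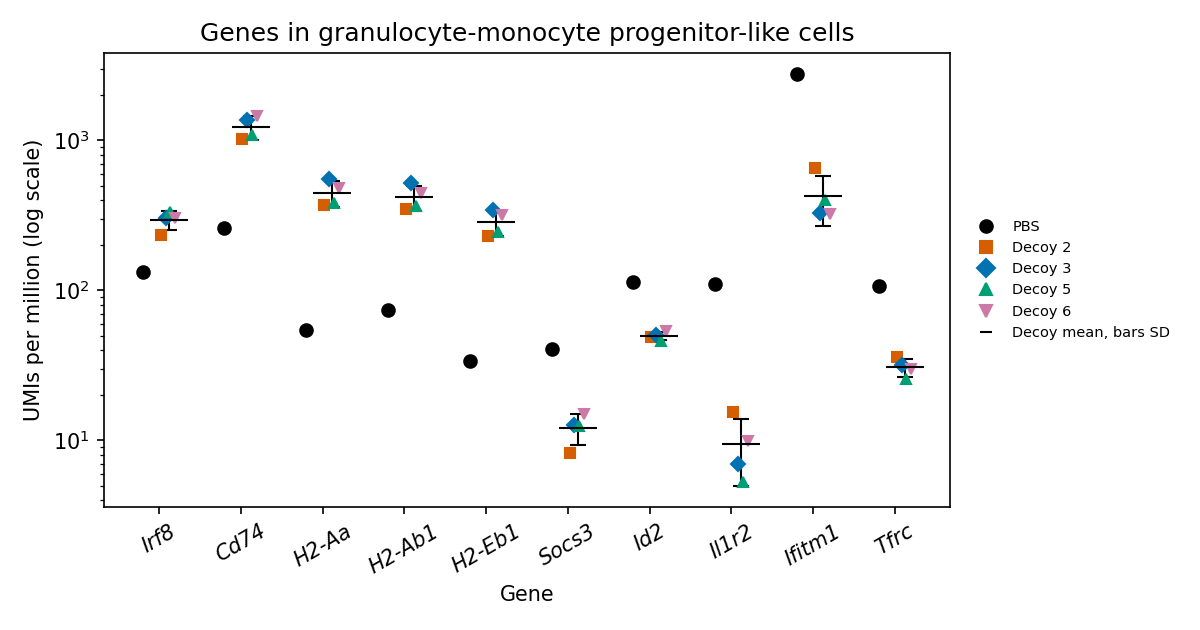
Levels (CPM, log axis) of 10 genes in the granulocyte-monocyte progenitor-like class, with a point per library and the Decoy mean with SD (n = 4). H2-Aa stands at 54.4 in PBS and 448 on average in Decoy, Irf8 at 132 and 294, and Socs3 at 40.4 and 12.1.

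Of 11230 genes tested in this class, 67 were called higher and 68 lower. DESeq2 called 371, and the count was 226 with the highest doublet scores removed at the expected rate, 559 without Decoy 2, 16 without Decoy 3, 60 without Decoy 5 and 61 without Decoy 6. The Irf8 call was lost without Decoy 3 (adjusted p = 0.111), Decoy 5 (0.0752) or Decoy 6 (0.0894) and with voom (0.0585). The Socs3 call was lost without the same 3 libraries (0.0901, 0.0752 and 0.0526). Without Decoy 3 those of Cd74 (0.0552), Ifitm1 (0.0565), Il1r2 (0.0567), Ccl4 (0.0636) and Sox4 (0.0783) were lost, without Decoy 5 that of Ccl4 (0.0503), and without Decoy 6 those of Il1r2 (0.0525) and Sox4 (0.0624). Without Decoy 2 Cd34 (adjusted p = 0.0259) and Mpo (log2 fold change 0.62, adjusted p = 0.0259) were called. H2-Aa, H2-Eb1, H2-Ab1, H2-DMb1, Cfb, Lpl, Dmkn, Tfrc and Id2 were called under all 8 alternatives. Subtracting the level of neutrophil-like cells of the same library, which should lack MHC class II, moved the log2 ratio of H2-Aa from 3.06 to 2.91, that of Cd74 from 2.24 to 2.06 and that of Irf8 from 1.17 to 1.13. Igkc, a B cell and plasma cell gene, moved in the same cells, from 4.09 CPM in PBS to 23.7, 588, 402 and 83.8 in the Decoy libraries, and C1qa of macrophages stood at 21.6 in PBS and 8.88, 21.7, 44.6 and 53.3.

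In this class 10 lists were called. MHC class II presentation had a median log2 fold change of 1.52 (adjusted p = 3.11e-07, 6 of 15 called, 9 adjusted over the list alone) and MHC class I presentation of 0.58 (7.19e-13, 8 of 19 called, 18 adjusted over the list alone). The interferon gamma response (median 0.59, 1.61e-08) and the type I interferon response (0.68, 2.66e-06) had 2 called members each, and 14 and 11 adjusted over the list alone. STAT3 targets were lower in 16 of 21 members (median -0.48, adjusted p = 0.000674), with Socs3, Il4ra and the AP-1 gene Junb called and 9 adjusted over the list alone. The stem and leukaemia programme was higher in 12 of 17 members (0.69, 0.00121), with 1 called, Sox4, and 5 adjusted over the list alone. Respiratory chain nuclear subunits were higher (0.17, 6.91e-07, 4 called, 21 adjusted over the list alone). G2 and M phase (-0.18, 0.000674), p53 and apoptosis (-0.23, 0.0287) and glycolysis and hypoxia (-0.18, 0.0415) were lower, with 0 called. With an estimated correlation all were lost, at adjusted p = 0.422 for both MHC lists, the interferon gamma response, STAT3 targets and the stem programme, 0.508 for the type I interferon response, the respiratory chain and glycolysis, 0.628 for p53 and 0.754 for G2 and M phase. fry called 3 lists, MHC class I (adjusted p = 0.036), MHC class II (0.0405) and STAT3 targets (0.0405).

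The other 11 lists were not called in this class, among them TLR9 pathway components (adjusted p = 0.812), the NF-kB and TLR response (0.892), myeloid differentiation regulators (0.759), chromatin and DNA methylation regulators (0.759), S phase (0.106), granule proteins (0.935), the unfolded protein response (0.552), checkpoint genes (0.812), immediate early genes (0.812), ribosomal proteins (0.924) and mitochondrial transcripts (0.979). In 6 of these, NF-kB, chromatin, granule, checkpoint, ribosomal and mitochondrial, the median, the mean and the test differed in sign.

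Effects in the progenitor-like and the mast cell and basophil-like class were compared directly for the 16 fixed genes. The log2 fold change in the progenitor-like class minus that in the mast cell and basophil-like class was -2.65 for Socs3 (adjusted p = 0.0154 over these genes), -1.5009 for Id2 (1.13e-04), -1.49 for Mpo (0.0428) and 2.27 for Cd34 (0.0154). For Irf8 it was 0.05 (adjusted p = 0.956). With library as a block, in the 4 libraries that held both classes, the values were -2.88 (0.00170), -1.52 (0.000519), -1.84 (0.000519) and 1.998 (0.0243). Without Decoy 3 the calls of Socs3, Mpo and Cd34 were lost (adjusted p = 0.0575 for each), as was that of Mpo without Decoy 6 (0.104). With RNA of other cells taken out, Mpo in the mast cell and basophil-like class kept 0 of 69 UMIs in PBS and 0 of 100 in Decoy 2. Socs3 kept 91 of 114 and 42 of 52, and Id2 22701 of 22817 and 10412 of 10485. Irf8 kept 64 of 182 in PBS, 4 of 107 in Decoy 2, 0 of 13 in Decoy 3 and 12 of 51 in Decoy 6. The difference of 0.05 for Irf8 therefore does not show an equal rise in both classes. Over all 12836 genes tested 7 differed, against 297 without Decoy 2, 0 without Decoy 3, 1 without Decoy 6 and 14 with the block, and Id2 was called (adjusted p = 0.0225) whereas Socs3 was not (0.242).

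In the macrophage-like class, some chemokine genes and interferon genes rose while ribosomal protein genes fell. Cd74 was called lower too, a call lost with the highest doublet scores removed. The NF-kB and TLR response as a list was not called (adjusted p = 0.837), with 12 members higher and 12 lower, of which 5 and 6 passed adjusted over the list alone. S100a9 rose from 51.6 to 1239 ± 484 CPM (SD, n = 4, log2 fold change 4.58 ± 0.60, SE, adjusted p = 0.0276), and Ccl5 from 154 to 1430 (3.21 ± 0.46, 0.0302). Ccl4 (2.40), the transcription factor Maf (2.12), the cytokine gene Tnf (1.73), Irf7 (1.30), the checkpoint ligand gene Cd274 (1.06) and B2m (0.66) rose. Sparc (-5.64), Igfbp7 (-4.94), Timp1 (-4.89) and Tfpi (-4.40) were among the genes with the largest falls. In this class 71 of 126 PBS cells lay in another cluster than most Decoy cells. The other 55 shared the main Decoy cluster, whose higher median depth may give them more weight in the sums. Other genes called lower were Rsad2 (-2.40), the cell cycle inhibitor gene Cdkn1a (-1.48), H2-Ab1 (-0.84) and Cd74 (-0.60 ± 0.11, SE, 7182 to 4725 CPM). Genes of T cells and neutrophils differed too, with Cd3e at 0 CPM in PBS and 25.5 in Decoy, Trbc2 at 0 and 72.04, and the granule gene Ngp at 1.40 and 246. Irf8 (log2 fold change -0.28, adjusted p = 0.256) and Stat3 (0.23, 0.28) were not called.

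Of 13429 genes tested in this class 279 were called higher and 268 lower. With the highest doublet scores removed at the expected rate the count was 284, Rsad2 stood at 0.0050 (adjusted p = 0.998), and the calls of S100a9 (0.169), Cd74 (0.155), H2-Ab1 (0.112), Cdkn1a (0.1196), Ngp (0.424), Cd3e (0.0713), Trbc2 (0.0643), Tnf (0.0695) and B2m (0.0520) were lost. DESeq2 called 934, voom 212, and the count was 1573 without Decoy 2, 0 without Decoy 3 (2497 at unadjusted p under 0.05), 39 without Decoy 5 and 45 without Decoy 6. Of the lists, 5 were called. Cytosolic ribosomal proteins were lower (median log2 fold change -0.42, adjusted p = 3.87e-11, 33 called, 55 adjusted over the list alone), as were MHC class II presentation (-0.62, 0.0236, 3 called lower and 1 higher, 7 lower and 2 higher adjusted over the list alone) and the stem programme (0.0455). The type I interferon response (0.57, 0.00237) and the interferon gamma response (0.0493) were higher. All 5 calls were lost with an estimated correlation (adjusted p = 0.952), and fry called ribosomal proteins (0.0452) and p53 and apoptosis (0.0141).

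In the B cell-like class the switched immunoglobulin gene Ighg2b (ENSMUSG00000076613, chromosome 12, 113302965 to 113307933, - strand) rose from 31.6 to 307 CPM (log2 fold change 3.28 ± 0.30, SE, adjusted p = 0.0443, n = 4), while Vpreb3, a gene of B cell development, fell by 1.94. Ighg2b was also among the leading genes of the plasma cell-like class, which held 0 cells in PBS and 37, 80, 199 and 83 in the Decoy libraries. Lists of cell division and respiration were higher, with medians of 0.80 for S phase (adjusted p = 8.14e-10, 24 adjusted over the list alone), 0.47 for G2 and M phase (4.83e-05) and 0.33 for the respiratory chain (7.31e-07, 27 adjusted over the list alone). MHC class II presentation was lower (-0.27, 0.0177, 6 adjusted over the list alone). These 4 calls were lost with an estimated correlation (adjusted p = 0.929), and fry called 0. Of 11055 genes tested 2 were called higher and 6 lower, while DESeq2 called 200, voom 25 and edgeR 244 with the highest doublet scores removed at the expected rate. The count was 0 without Decoy 2, without Decoy 3 or without Decoy 5 and 6 without Decoy 6, and 1568 genes had an unadjusted p under 0.05.

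Cycling cells were called from S phase and G2 and M phase genes at equal depth. They made up 75.6% of cells in PBS and 76.8%, 51.2%, 42.7% and 54.7% in the Decoy libraries, a mean of 56.3% ± 14.5 (SD, n = 4, exact permutation p = 0.6). Within the mast cell and basophil-like class they made up 77.2% in PBS and 72.8% ± 6.03 in Decoy (SD, n = 3, exact permutation p = 1). In the other classes the shares were 48.3% and 46.2% ± 6.48 (SD, n = 4, exact permutation p = 0.8), and without thinning the difference turned to 9.75 points higher in Decoy (exact permutation p = 0.2). Free RNA can enter phase calls and differed between the libraries, so its part in these shares is open.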

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

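The tests of host cells, leukaemic identities, droplets holding 2 cells and a shift of the whole PBS library were chosen only after the results they bear on were seen. In a search of 48 values for a Decoy library far from the other 3, 2 stood apart, and chance would mark about 1 in 20. The total UMI count of Decoy 2, 234251245, stood apart from 56490098 to 85354471 in the others. The level of Cbfb in the progenitor-like class of Decoy 6, 52.996 CPM, stood apart from 47.3 to 48.2 in the others. The log2 fold change in the progenitor-like class minus that in the mast cell and basophil-like class was -2.65 for Socs3, -1.49 for Mpo, -1.5009 for Id2 and 2.27 for Cd34, and each passed an interaction test adjusted over the 16 fixed genes. For Mpo, 0 of its 69 PBS UMIs in the mast cell and basophil-like class were left with RNA of other cells taken out. Barcodes left out for a high mitochondrial share were used only by the alternative with all barcodes. They made up 12.3% of the barcodes in Decoy 3, 16.2% in Decoy 5 and 11.2% in Decoy 6, above the 8.34% of PBS.

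For the differences over all kept cells, a change in the mix of cell classes and a difference by chance between libraries were set against a response within cells. Expected fold changes were computed from the share of UMIs in each class, with every class at its mean profile over libraries. Over the 1671 genes at unadjusted p under 0.05 they correlated with those observed at r = 0.741. Of these genes 98.9% had the same direction, and the slope was 1.05. Over all 16001 genes r was 0.915, and genes are not independent replicates. The bounds set beforehand for the 1671 genes were 0.8 for the mix as the cause and 0.5 against it. At r = 0.741 a mix and a response within classes cannot be told apart. The median log2 fold change of these genes was 4.51 observed and 3.89 computed from the shares. In the mast cell and basophil-like class Irf8 stood at 0.366 CPM in PBS and 0.517 in Decoy 2, and Cd74 at 4.82 and 4.76. In the other named classes Irf8 stood at 123 and 189, and Cd74 at 1765.5 and 2019, each scaled by the total alone. A smaller share of the first class therefore raises both genes over all kept cells. All 5 choices of the single library called 0 genes, the highest other count being 0, which a real count of 0 fixes and which decides nothing, as 5 choices are also too few for a share under 0.05. At unadjusted p under 0.05 the counts were 1671 for PBS as the single library, 1275 for Decoy 5, 166 for Decoy 2, 59 for Decoy 3 and 16 for Decoy 6.

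For the larger share of cells outside the mast cell and basophil-like class in the Decoy libraries, host cells, leukaemic cells that took on these identities and droplets with 2 cells were weighed. Of 5573 cells of these classes in the Decoy libraries with UMIs of Xist or of Y-linked genes but not both, 98.3% had the Y-linked genes, whereas in PBS 0 of 14584 such mast cell and basophil-like cells did, so cells of the host mice fit if the hosts were male and the leukaemia female, which is not given in the sources used here. Host cells lack GFP and most should lack c-Kit, so the sort for both should have removed them, and its purity and gates were not given either. Leukaemic cells with new identities are excluded as the main source, since 1.74% of these cells had Xist alone, a share weighted to Decoy 5 that was highest at 9.83% in Decoy 2, provided that such cells keep Xist and gain no Y-linked RNA. Droplets with a leukaemic and another cell are excluded as the main source in Decoy 3, Decoy 5 and Decoy 6, where Xist in these classes together was at most 6.63% of the mast cell and basophil-like level. Decoy 5 held 0 cells of that class, so the mean of the other libraries (993 CPM) was its reference. The low Xist level there follows from the absence of that class. Such droplets remain open in Decoy 2 (14.0%) and for T cell-like (16.3%) and neutrophil-like cells (12.3%) of Decoy 6. The values are consistent with fewer GFP-positive leukaemic cells after treatment leaving a larger share of host cells in the sort, and the numbers of sorted cells needed to test this were not among the files.

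For the genes changed within the mast cell and basophil-like class, RNA of other cells, a shift of the whole PBS library and chance were set against a response to treatment. After the profile of the other classes was taken out, 57 of the 91 higher genes, 62.6%, stayed called and 12 were no longer tested. The median log2 fold change of those called at first went from 1.24 to 0.95, which leaves RNA of other cells open. Igkc and Cd74 turned lower, and S100a8 and S100a9 kept 0 UMIs in every library, PBS included. A step that leaves 0 on both sides cannot show whether it accounts for the difference of these granulocyte genes. Its scale rested on 111 Y-linked UMIs in PBS and 39, 8 and 23 in Decoy 2, Decoy 3 and Decoy 6. Genes still called higher had a median of 0.78 in B cell-like cells, 79.2% of the 0.98 in the mast cell and basophil-like class, with 47 of 52 higher, so a shift of the whole PBS library fits for most of these genes, and a response of every class would give the same. The lower genes Tfrc and Erh follow it too, lower in each of 5 other classes by -1.79 to -0.67 and -1.07 to -0.51. Some interferon-induced genes had unlike values in the separate fits, though their differences between classes were not tested. Oasl2 (1.92 ± 0.25, SE, in the class) stood at -0.33 ± 0.54 in B cell-like, 0.34 ± 0.31 in macrophage-like and 0.69 ± 0.21 in progenitor-like cells. In neutrophil-like cells it stood at 1.77 ± 0.31 and in T cell-like cells at 7.14 ± 1.97. Xaf1 (1.42 in the class) stood at 0.17 ± 0.18 in B cell-like, 0.33 ± 0.15 in progenitor-like, 0.44 ± 0.53 in T cell-like, 0.47 ± 0.28 in macrophage-like and 1.14 ± 0.25 in neutrophil-like cells. Ifitm3, also called higher in the class, stood at 2.34 ± 0.70 in B cell-like, 4.21 ± 0.51 in T cell-like and 1.00 ± 0.27 in neutrophil-like cells. In macrophage-like cells it stood at 0.35 ± 0.22 and in progenitor-like cells at -0.52 ± 0.12. Whether an equal shift accounts for Oasl2, Xaf1 and Ifitm3 stays open. The real choice of the single library called 100 genes and the highest other choice 4, but 4 choices are too few for a share under 0.05. A second PBS library would separate the shift from a response.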

How the results depend on the processing

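The repeats with doublets removed at the expected rate, with RNA of other or leukaemic cells taken out, those of the differences between classes, and all those of lists within classes and of the classes outside the mast cell and basophil-like one were chosen only after the data had been seen. Of the results with a direction, 252 of 269 repeats of named genes over all kept cells, 585 of 651 in the mast cell and basophil-like class, 311 of 400 in the progenitor-like class, 220 of 432 in the macrophage-like class and 26 of 47 in the B cell-like class kept their direction and their side of the threshold. So did 148 of 189 repeats of lists over all kept cells, 105 of 147 in the mast cell and basophil-like class, and 60 of 77 of differences between classes. Class shares kept their direction in 102 of 104 repeats and cycling shares in 15 of 17, where no test could pass. At the depth and spread of these libraries, the simulation missed most 2-fold changes over all kept cells and in the T cell-like, neutrophil-like, B cell-like and macrophage-like classes. Depth and spread were not varied apart. No paired analysis was possible because the single PBS library has no partner among the Decoy libraries. The planned clustering on variable genes without the genes called was not run as 0 genes were called, and genes at unadjusted p under 0.05 were left out in its place. At resolution 0.3 no cluster was named progenitor or conventional dendritic, at 1.0 or with 2000 cells per library none was named conventional dendritic, and without the genes at unadjusted p under 0.05 neither name was given. PBS could not be left out, and Decoy 5 was not in the fit of the mast cell and basophil-like class.

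Counts of called genes moved as follows, and the cause was not tested. DESeq2 called 2076 over all kept cells, 260 in the mast cell and basophil-like, 200 in the B cell-like, 89 in the T cell-like, 371 in the progenitor-like, 934 in the macrophage-like and 32 in the neutrophil-like class. The voom method called 257 in the mast cell and basophil-like, 25 in the B cell-like and 212 in the macrophage-like class. In the mast cell and basophil-like class the robust fit called 189, no gene filter 536, a mean of at least 10 CPM 27, thinned sums 61, the stricter cell filter 64, removal of doublets at the expected rate 64 and taking out RNA of other cells 65. With doublets removed at the expected rate the count was 244 in the B cell-like, 21 in the T cell-like, 226 in the progenitor-like, 284 in the macrophage-like and 6 in the neutrophil-like class. With RNA of leukaemic cells taken out the count was 144 in the B cell-like, 61 in the T cell-like and 324 in the progenitor-like class. Leaving out 1 Decoy library gave 0 to 2466 over all kept cells, 151 to 645 in the mast cell and basophil-like, 0 to 6 in the B cell-like, 0 to 49 in the T cell-like, 16 to 559 in the progenitor-like, 0 to 1573 in the macrophage-like and 0 to 1 in the neutrophil-like class. With an estimated correlation 0 lists were called in every fit. fry called 0 over all kept cells and in the mast cell and basophil-like, B cell-like and neutrophil-like classes, 2 in the T cell-like, 9 in the erythroid-like, 3 in the progenitor-like and 2 in the macrophage-like class.

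Direction reversed in few cases, and the cause was not tested. In the mast cell and basophil-like class alone, against all kept cells, glycolysis and hypoxia (adjusted p = 0.0595), ribosomal proteins (9.27e-05) and the respiratory chain (7.07e-06) turned higher. Within that class the stem and leukaemia programme turned with fry (0.996) and MHC class II with RNA of other cells taken out (0.720). Without 1 Decoy library in turn, adjusted p ran from 0.599 to 0.907 for the stem programme, 0.413 to 0.924 for p53, 0.0768 to 0.720 for S phase and 0.528 to 0.720 for mitochondrial transcripts. The difference in unnamed cells ran from -0.272 to 0.4926 points, and that in cycling cells of other classes was 3.47 at 1500 UMIs and 9.75 unthinned. Over all kept cells Cbfb turned to 0.012 at a mean of at least 10 CPM, and Stat3 to -0.023 with no gene filter and -0.012 to 0.062 without 1 library. In the mast cell and basophil-like class, library size alone gave Cbfb -0.019, and taking out RNA of other cells gave Igkc -1.63, Cd74 -2.11, Irf8 -0.36 and Dnmt1 0.0043. Dnmt1 was 0.0012 at a mean of at least 10 CPM, 0.0023 with doublets removed at the expected rate and -0.072 to 0.024 without 1 library. Kit was 0.091 after thinning, 0.083 with the stricter cell filter and -0.11 to 0.022 without 1 library, and Runx1 -0.12 to 0.014. In the progenitor-like class Cebpa ran from -0.28 to 0.023 without 1 library, and Runx1 was 0.073 with RNA of leukaemic cells taken out. With doublets removed at the expected rate Runx1 was 0.014 and Ccl4 2.10 in that class, and Rsad2 0.0050 in the macrophage-like class. The difference between classes turned for Irf8 (-0.44 to 0.40 without 1 library, -0.15 with the block), Gata2 (-0.090 to 0.12, -0.054 with the block), Runx1 (-0.030 to 0.15) and Myc (-0.078 to 0.16).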

Other observations

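The test of leukaemic RNA given here was set before its result was seen. In the T cell-like class the lists of MHC class II, cell division and interferon genes were called higher in the Decoy libraries by camera. Of 10339 single genes, 0 were called by edgeR or voom and 89 by DESeq2. By edgeR 21 were called with doublets removed at the expected rate and 49 without Decoy 2, and 1129 had an unadjusted p under 0.05. The median log2 fold change was 3.51 for MHC class II presentation (adjusted p = 4.29e-11, 11 members adjusted over the list alone), 0.69 for G2 and M phase (1.04e-11, 21 members), 0.41 for S phase (7.56e-07, 8 members) and 0.55 for MHC class I presentation (3.49e-05, 9 members). The interferon gamma response (0.0106) and the type I interferon response (0.0155) were called too. Genes of other cells moved with these, as Igkc stood at 67.1 CPM in the T cell-like cells of PBS and 268 to 1071 in Decoy, and the macrophage gene C1qa at 8.39 and 19.1 to 51.0. With an estimated correlation the S phase list had adjusted p = 0.32 and the others 0.849, and fry called MHC class II presentation (0.0487) and S phase (0.0132). In the neutrophil-like class edgeR called 0 of 9424 genes, voom 0, DESeq2 32 and edgeR 6 with doublets removed at the expected rate, with 599 at unadjusted p under 0.05. There 7 lists were higher, with medians of 3.91 for MHC class II presentation (adjusted p = 8.28e-09), 1.07 for the interferon gamma response (1.58e-10), 0.96 for the type I interferon response (6.36e-13) and 0.59 for MHC class I presentation (9.6e-09), with Igkc at 1.90 CPM in PBS and 47.1 to 21776 in Decoy in the same cells, which should lack it and MHC class II, followed by the NF-kB and TLR response (0.00801), STAT3 targets (0.0142) and myeloid differentiation regulators (0.0342). With an estimated correlation these had adjusted p = 0.638 for the first 4 and 0.666 for the last 3, and fry called 0.

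In the erythroid-like class, compared in PBS, Decoy 3, Decoy 5 and Decoy 6, 1992 genes were higher and 2687 lower in Decoy. Most PBS cells of this class came from another cluster than most Decoy cells. Genes of the integrated stress response were among those lower, with log2 fold changes of -9.42 for Gdf15, -6.83 for Atf5 and -6.01 for Trib3. The lists lower were the type I interferon response (adjusted p = 0.00204), p53 and apoptosis (0.013) and the unfolded protein and integrated stress response (0.023), and MHC class I presentation was higher (0.00245). All 4 had adjusted p = 0.613 with an estimated correlation, and fry called 9 lists.

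Genes called higher in the mast cell and basophil-like class had short transcripts, with 33.0% of them under 1000 bases of exons against 7.09% of all genes tested. Genes called lower had a median of 2618 bases. In Decoy 3 25 of 198 progenitor-like cells had Xist and no Y-linked UMI, at a median of 3365 UMIs per cell. They had Mpo at 74.8 CPM, against 1001 in the cells with Y-linked UMIs alone, the immunoglobulin gene Igkc at 6574 and the haemoglobin gene Hba-a1 at 9382. PBS had 1 such cell, Decoy 2 10, Decoy 5 0 and Decoy 6 1. No 2 libraries had like profiles, with chi-square over degrees of freedom from 88.2 to 4630.

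RNA of leukaemic cells in the droplets was tested as the source of genes that were lower in Decoy in the other classes. After the leukaemic profile, scaled by Xist, was taken out, 100% of the genes called lower stayed called in the B cell-like class (6 of 6) and in the progenitor-like class (68 of 68), 93.3% in the macrophage-like class (250 of 268) and 97.2% in the erythroid-like class (2612 of 2687), which excludes it as their main source. The share of RNA from leukaemic cells estimated from Xist was 31.7% in T cell-like, 21.1% in B cell-like and 11.4% in progenitor-like cells of Decoy 2, against 14.7%, 7.29% and 5.06% in PBS and 0 in Decoy 5. In macrophage-like cells it was highest in PBS, at 11.6% against 10.1% in Decoy 2.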
